A study of Mus musculus with 7 samples.

How the data were processed

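The series holds 7 arrays of total RNA from sorted mouse bone marrow stromal cells, 3 labelled Ocn+ and 4 labelled Osx+. Per the labels' protocols, RNA was extracted with Trizol, amplified as cDNA by the NuGEN Ovation V2 single-primer method, fragmented and labelled with biotin. Linear amplification of this kind favours the 3' end of transcripts, so RNA integrity can change the signal of probe sets placed far from that end. The deposited table gives 1 log2 expression value per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes arrays and summarizes the probes of a set. The software and its version are not given in the sources used here. The log2 values of all arrays ran from about 3 to 15 with nearly equal medians (8.25 to 8.35), and no filter on dim probe sets was seen. No detection calls were used here, so whether a dim signal lies above background is not known, and a difference against one is a difference of measured signals. Quantile normalization forces equal distributions, so a change of total RNA per cell cannot be read from these values. An array has no read depth; precision comes from the number of arrays, 3 against 4.

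Of 22690 probe sets 64 were controls. Probe sets were named from the platform annotation, in which 20380 had 1 gene symbol, 691 had several and 1555 had none listed; 20351 of the first were matched to a current symbol by Entrez identifier. Only probe sets with 1 symbol were used, which left the osteocalcin genes and some list members not analysed here. Each gene was represented by its probe set of highest mean over the 7 arrays, giving 12393 genes. No coordinates are given, since the table names no genome build.

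Groups came from the sample titles and the cell type label. The comparison was Ocn+ minus Osx+ in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, constant prior, no block), 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A fold is given as the brighter group mean over the dimmer on the linear scale. The 41 gene lists held 828 different genes, 735 of them measured. Each list was tested with camera at a preset correlation of 0.01 and adjusted over the 41 lists, and list adjusted p-values in the report are camera's unless another test is named. Camera with an estimated correlation and fry were alternatives. By fry 2 lists were called, and by its test for change in either direction 3. Per list, members were also adjusted over the list alone. List means per array were compared by an exact permutation test, 2-sided, whose smallest p with 3 against 4 is 0.0571. The mean, median and test of 3 lists differed in sign, namely the collagens, lymphoid support and adipocyte lists.

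Before the data were examined, the design, the lists, the alternatives and the rule for named genes were fixed. The rule took Sp7, the osteocalcin genes and Dll4, then the 12 genes of largest change per direction among those that passed without overlap. Where fewer than 5 passed, it took the 12 of smallest p per direction, leaving out predicted genes, clone names, receptor segments, olfactory receptors and small RNAs, and said not to pass. From each list it took up to 4 called members, or the 2 of smallest p. Since 0 genes passed, the smallest p decided. Genes outside the rule are said to be chosen after their values were seen, apart from the Notch receptors and ligands, which are members of a fixed list and were also picked from it after their values were seen. The Xist class (log2 signal under or over 8) was defined after seeing the data, as were the fits that use it.

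The alternatives fixed in advance were the replicate number as a block, leaving out each array in turn, leaving out genes under the 25th percentile or the median of signal, quantile normalization, median centring, a trended robust prior, array weights, the mean of all probe sets or the probe set of largest variance per gene, all probe sets, a fold limit of 1 log2 unit, a threshold of 0.1, an estimated correlation and fry. Added later were the Xist class as a term and fits within each class.

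The fit was tested on simulated data with the real means and spreads of 12393 genes, 3 against 4 arrays, 200 changed genes and 20 runs. At the threshold of 0.05 it recovered 19.5% of genes changed by 1 log2 unit, 77.9% of those changed by 2 and 96.7% of those changed by 4, with 6.75 false calls per run. A list shifted by 1.5 log2 units was called in 20 of 20 runs, with 0.2 other lists called per run. The simulated noise was independent between genes and equal in both groups. In the real data the estimated correlation within the endothelial list was 0.52. The simulated list rates therefore do not give camera's error rate for the real lists. The changed genes were chosen at random, so the recovery rates do not give the power of the real comparison either.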

Results

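Gene expression was measured on 7 Affymetrix mouse arrays of osteolineage cells sorted from bone marrow stroma by flow cytometry. The animals were double transgenic mice with tamoxifen-inducible reporters. Cells marked through the osterix promoter (Osx+, osterix being the product of Sp7) were red, and cells marked through the osteocalcin promoter (Ocn+) were green. Osterix is a transcription factor of cells committed to bone formation, and osteocalcin is a matrix protein of mature osteoblasts. Cells were sorted 6 days after tamoxifen from mice 4 to 6 weeks old. The Ocn+ group had 3 arrays and the Osx+ group 4, and cells with both colours were not analysed here. Nothing in the labels says which arrays came from the same animal or whether each came from a separate one, so p-values measure only the spread between these samples, which may be technical. The median log2 signal of an array lay between 8.25 and 8.35, and the number of arrays limits the precision of every value. The comparison asks which transcripts set osteocalcin-marked cells apart from osterix-marked cells. Bone cells as a source of Notch signals for lymphoid progenitors are background to it, which is why the Notch ligand Dll4 was among the genes fixed in advance.

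The Ocn+ arrays carried more signal for markers of endothelium, neutrophils and osteoclasts and for the Notch ligands and receptors, and less for markers of macrophages and cartilage, in a test that took genes of a list as nearly uncorrelated. Camera called these 6 lists with its preset correlation of 0.01 and 0 of them with an estimated correlation, where their adjusted p was 0.356 to 0.432. The 20 endothelial markers were on average 1.99 log2 units higher in Ocn+ cells (SE 0.69). The 17 measured neutrophil markers were 1.72 higher (SE 0.66), the 12 osteoclast markers 1.18 higher (SE 0.46), and the 10 Notch ligands and receptors 0.75 higher (SE 0.29). The difference was -0.82 (SE 0.39) for the 21 macrophage markers and -1.05 (SE 0.65) for the 16 cartilage markers. The arrays of the groups overlapped in the list means of the Notch ligands and receptors (2-sided exact permutation p = 0.114) and of the cartilage markers (0.286), and not in the other 4. For the macrophage markers the groups were apart by a narrow margin, with Ocn+ replicate 3 at 10.62 and Osx+ replicate 4 at 10.64. Genes of early bone-forming cells did not pass as a list, and Alpl, the alkaline phosphatase of mineralizing cells, chosen after its values were seen, stood at 13.81 ± 0.07 in Ocn+ cells (SD, n = 3) and 13.69 ± 0.06 in Osx+ cells (SD, n = 4).

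These differences were found for groups of genes and not for single genes. Of 12393 genes, 0 had an adjusted p under 0.05 in limma, and 658 had an unadjusted p under 0.05, where chance gives 620. Of the 658 genes, 431 were higher and 227 lower in Ocn+ cells. The smallest adjusted p was 0.108, for Gata2. The values of the 3 Ocn+ and 4 Osx+ arrays did not overlap for 855 genes, or 6.90%, against the 5.71% that chance gives. With arrays weighted by their fit, limma called 97 genes, 78 of them higher in Ocn+ cells. The weights ran from 0.24 for Osx+ replicate 1 to 6.02 for Ocn+ replicate 2, and the largest in the Osx+ group was 2.16, for replicate 4. They were estimated from the same arrays and then taken as known. The weighted fit therefore rests mainly on few arrays, and its calls are no independent support for a gene. With equal weights limma called 3 genes without Osx+ replicate 2 (Ctsg, Elane and Prtn3). It called 3 without Osx+ replicate 3 (Oscar, Ckmt1 and Tspan15, of which Ckmt1 and Tspan15 are named after their values were seen). Among 41 gene lists fixed before the data were examined, camera called 14 with its preset correlation of 0.01, of which 10 rose and 4 fell in Ocn+ cells. With an estimated correlation it called 0 of them, the smallest adjusted p being 0.356. The list means of the 3 Ocn+ and 4 Osx+ arrays did not overlap for 5 of the 14, and overlapped for the other 9, with exact permutation p from 0.114 to 0.629.

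The gene behind the osterix reporter did not separate the groups. Sp7 stood at 12.65 ± 0.35 in Ocn+ cells (SD, n = 3) and 12.47 ± 0.31 in Osx+ cells (SD, n = 4), a difference of 0.18 with a standard error of 0.25 and a limma adjusted p of 0.999. The osteocalcin genes Bglap, Bglap2 and Bglap3 were not analysed here, so no such comparison was made for the osteocalcin side. Whether Sp7 signal at the time of sorting reflects the reporter was not tested.

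Dll4, a ligand of Notch receptors, was 3.61-fold brighter in Ocn+ cells. Its log2 signal was 8.18 ± 0.29 in Ocn+ cells (SD, n = 3) and 6.33 ± 0.67 in Osx+ cells (SD, n = 4), and the groups did not overlap. The difference of 1.85 (SE 0.38) did not pass over all genes, with a limma adjusted p of 0.689, and passed adjusted over the list alone, at 0.0139. With arrays weighted by their fit, Dll4 passed over all genes (difference 2.05, limma adjusted p = 0.0303), the one setting tried in which it did. The other Dll4 probe set gave 6.95 ± 0.23 against 5.32 ± 0.42, a difference of 1.63. The Dll4 difference was 2.44 among high-Xist and 1.22 among low-Xist libraries, classes described with the array structure. The high-Xist class holds 2 Ocn+ and 2 Osx+ libraries and the low-Xist class 1 Ocn+ and 2 Osx+ libraries, so a low-Xist difference rests on a single Ocn+ library. Dll1, another Notch ligand, also passed adjusted over the list alone (0.0139), with a difference of 1.33 (SE 0.30).

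All 10 Notch ligands and receptors had a difference above 0, and as a list they rose in Ocn+ cells (camera adjusted p = 0.000361). The adjusted p was 0.356 with an estimated correlation, and the exact permutation p of the list mean was 0.114, with Osx+ replicate 3 (9.48) above Ocn+ replicate 2 (9.46). Among 10 members, 0 passed over all genes and 2 passed adjusted over the list alone. Notch4, a receptor of endothelial cells, differed by 2.22 (SE 0.84), and Notch3, a receptor of mural cells around vessels, by 0.81 (SE 0.35), while Jag1 differed by 0.15, Notch1 by 0.31 and Notch2 by 0.02. The endothelial list moved in the same arrays. The Notch list difference was 1.01 among libraries with high Xist signal and 0.58 among those with low Xist signal, and it was 0.31 (adjusted p = 0.310) with genes under the median signal left out. The 18 measured Notch targets and modifiers were 0.35 higher (adjusted p = 0.0764), a list that did not pass although its arrays did not overlap. It passed without Ocn+ replicate 1 (0.39, adjusted p = 0.0168) and without Osx+ replicate 4 (0.33, adjusted p = 0.0428). Heyl, a Notch target, differed by 1.64 (SE 0.39) and Hes1, another, by 0.94 (SE 0.32).

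**Figure D1:**
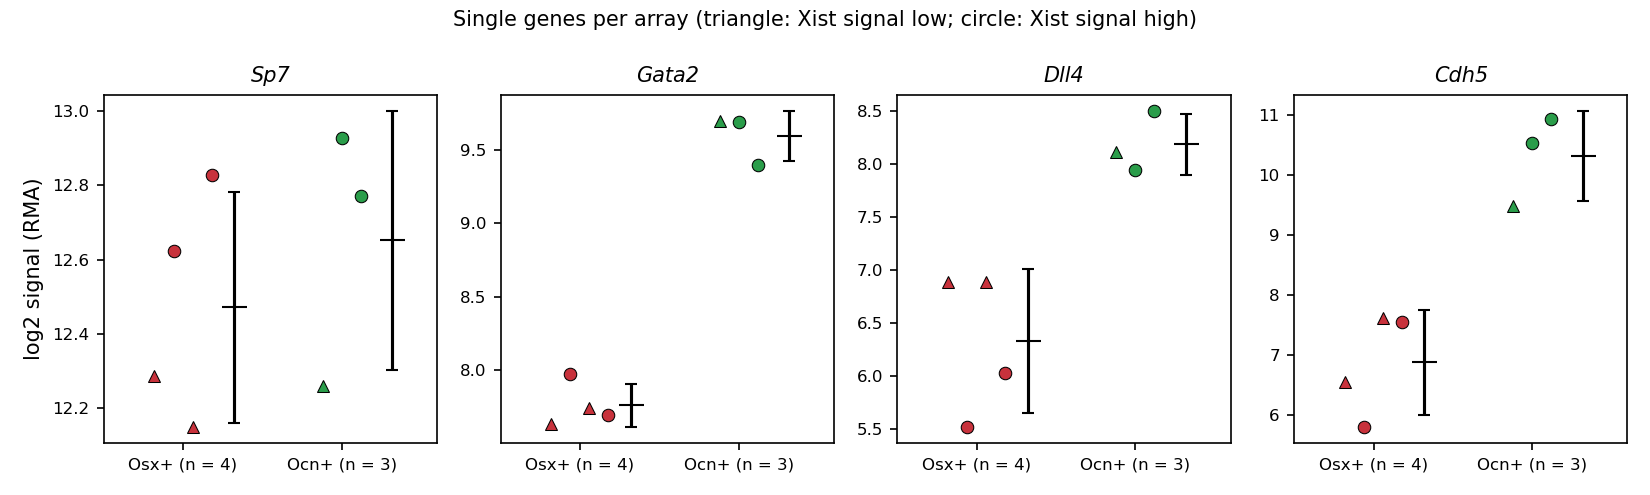
Log2 signal (RMA) of Sp7, Gata2, Dll4 and Cdh5 on each array, by group, with the mean and SD as bars; triangles are libraries with low Xist signal and circles those with high Xist signal. Sp7 overlaps between the groups, and the 3 Ocn+ arrays lie above the 4 Osx+ arrays for Gata2, Dll4 and Cdh5.

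The endothelial list had the largest mean difference of the 41 lists. The list mean was 9.61 ± 0.17 in Ocn+ cells (SD, n = 3) and 7.62 ± 1.16 in Osx+ cells (SD, n = 4), and 19 of 20 members had a difference above 0. The list rose in Ocn+ cells, with a camera adjusted p of 5.77e-14. Its adjusted p was 0.356 with an estimated correlation, and the 2-sided exact permutation p of the list mean was 0.0571, the smallest that 3 against 4 arrays can give. Over all genes 0 members passed, and 10 passed adjusted over the list alone. With array weights limma called 11 members over all genes, these 10 and Robo4, which is named after its values were seen. Cdh5, the cadherin of endothelial junctions, was 10.9-fold brighter in Ocn+ cells (log2 difference 3.44, SE 0.54). Flt4, a receptor of vascular growth factors, differed by 2.99 (SE 0.67). Pecam1, Plvap and Tie1, chosen after their values were seen, differed by 2.55, 2.92 and 3.12. The 4 Osx+ arrays ranged from 6.51 to 9.11 in the list mean, with replicate 3 nearest to the Ocn+ arrays. The difference was 2.89 among libraries with high Xist signal, 1.11 among those with low Xist signal and 2.18 with the Xist class in the model.

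Markers of granulocytes and osteoclasts were also higher. The neutrophil list stood at 10.06 ± 0.14 in Ocn+ cells (SD, n = 3) and 8.34 ± 1.11 in Osx+ cells (SD, n = 4), and 15 of 17 members had a difference above 0. It rose in Ocn+ cells, with a camera adjusted p of 7.83e-08, and the adjusted p was 0.356 with an estimated correlation. The 4 members brightest in Ocn+ cells were taken after values were seen. S100a9 differed by 0.54 (SE 0.44), S100a8 by 0.79 (SE 0.52) and Camp by 2.52 (SE 1.01). The last, Mmp9, also belongs to the osteoclast list and differed by 1.61 (SE 0.51). The serine proteases of azurophil granules were the members that passed adjusted over the list alone, 3 in number. Ctsg differed by 4.29 (SE 1.05), Prtn3 by 3.61 (SE 0.99) and Elane, chosen after its values were seen, by 3.64 (SE 1.01). In Osx+ replicate 2 Prtn3 stood at 9.78, and the other Osx+ arrays lay between 5.58 and 6.20. Without that array these 3 genes were the ones called over all genes. No detection calls were used here, so it is not known whether the lowest Elane values, 3.95 to 4.44 in the other Osx+ arrays, lie above background. The osteoclast list stood at 10.53 ± 0.21 in Ocn+ cells (SD, n = 3) and 9.35 ± 0.76 in Osx+ cells (SD, n = 4), with 12 of 12 members above 0. It rose in Ocn+ cells, with a camera adjusted p of 3.18e-07, and its adjusted p was 0.356 with an estimated correlation. Its 4 members that passed adjusted over the list alone were Oscar, an activating receptor of osteoclasts, Ocstamp, a protein of osteoclast fusion, the collagen-cleaving protease Ctsk and the gelatinase Mmp9. Their differences were 3.82, 2.92, 0.86 and 1.61, and Oscar, Ocstamp and Ctsk passed over all genes with array weights. The neutrophil difference was 1.79 among high-Xist and 1.57 among low-Xist libraries, and the osteoclast difference 1.66 and 0.80.

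Macrophage markers went the other way as a list. Their list mean was 10.32 ± 0.49 in Ocn+ cells (SD, n = 3) and 11.14 ± 0.51 in Osx+ cells (SD, n = 4), and 18 of 21 members had a difference below 0. The groups did not overlap, but only narrowly, with Ocn+ replicate 3 at 10.62 and Osx+ replicate 4 at 10.64. The list fell in Ocn+ cells by 0.82, with a camera adjusted p of 1.01e-06 and an adjusted p of 0.432 with an estimated correlation. Mpeg1, a pore-forming protein of macrophages, differed by -2.11 (SE 0.58) and Ms4a7 by -1.85 (SE 0.47), and 0 members passed adjusted over the list alone. The complement gene C1qa, chosen after its values were seen, differed by -1.60 (SE 0.65). The members brightest in Ocn+ cells, also taken after values were seen, moved less. Lyz2 and Lyz1 differed by -0.19 (SE 0.33) and -0.21 (SE 0.28), and Csf1r and Hmox1 by 0.28 (SE 0.38) and 0.41 (SE 0.20). The difference was -1.03 among high-Xist and -0.47 among low-Xist libraries, and -0.53 without Ocn+ replicate 2.

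Cartilage genes also stood lower in Ocn+ cells. The list mean was 9.93 ± 0.78 in Ocn+ cells (SD, n = 3) and 10.98 ± 0.89 in Osx+ cells (SD, n = 4), and 15 of 16 members had a difference below 0. The list fell by 1.05, with a camera adjusted p of 3.18e-07 and an adjusted p of 0.406 with an estimated correlation. Acan, the large proteoglycan of cartilage, differed by -0.70 (SE 0.24) and its binding partner Hapln1 by -1.71 (SE 0.70). Over all genes and adjusted over the list alone, 0 members passed. The groups overlapped, with an exact permutation p of 0.286. The difference was -0.61 without Ocn+ replicate 3 and -0.70 without Osx+ replicate 2, and it was -1.45 among high-Xist and -0.46 among low-Xist libraries.

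**Figure D2:**
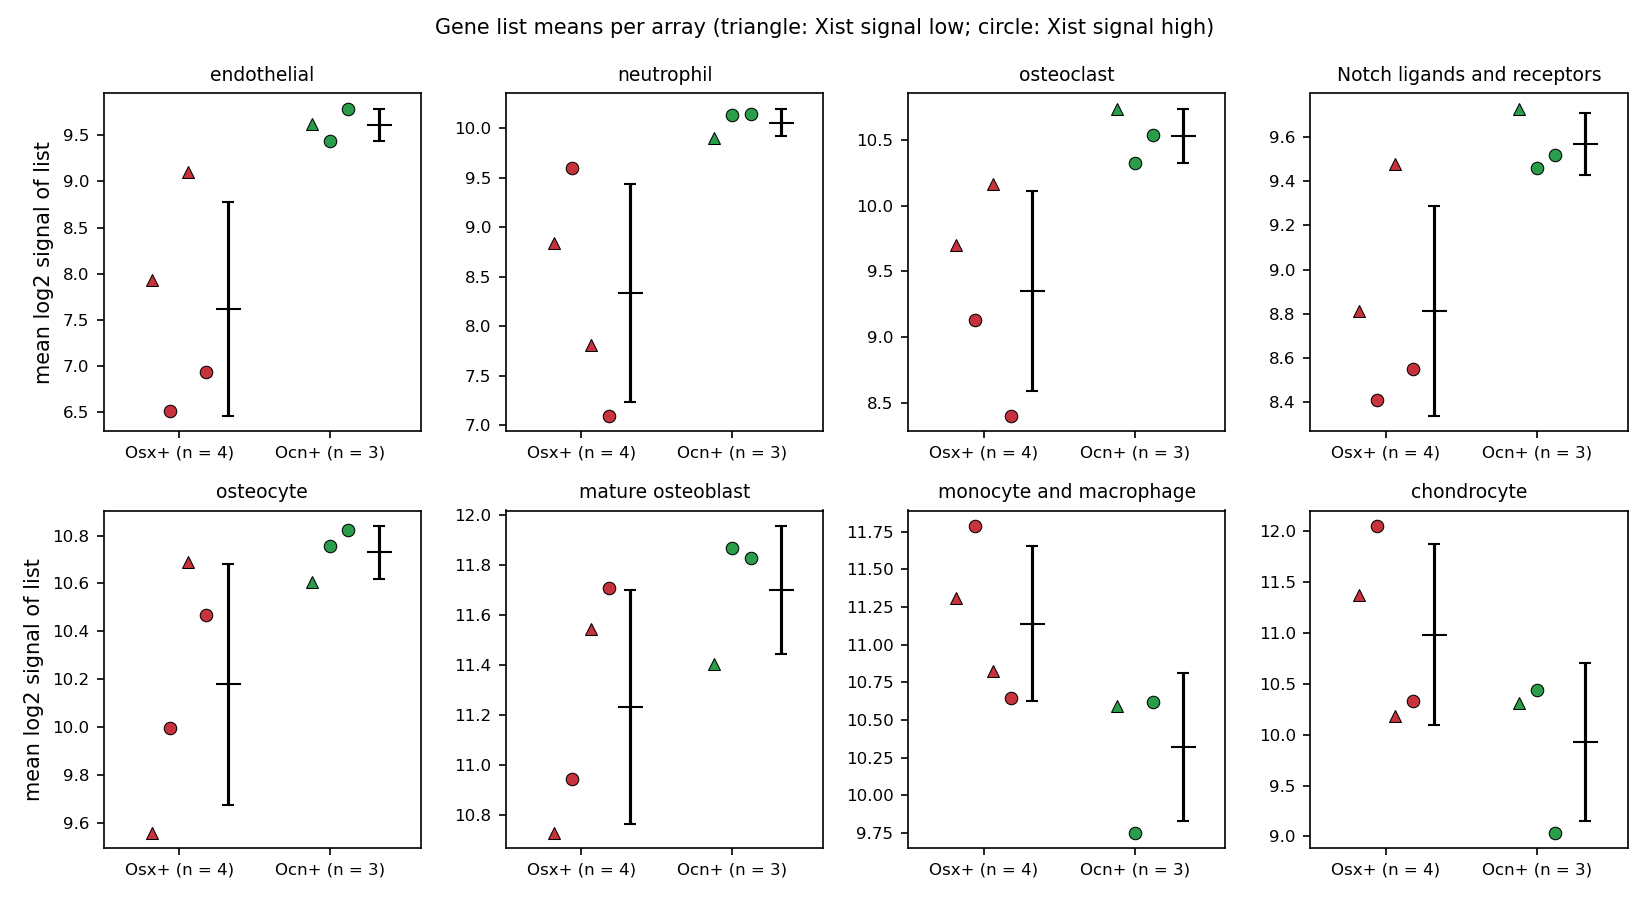
Mean log2 signal of 8 gene lists on each array, by group, with the mean and SD as bars; triangles are libraries with low Xist signal and circles those with high Xist signal. The 3 Ocn+ arrays lie above all 4 Osx+ arrays for the endothelial, neutrophil and osteoclast lists, and the Osx+ arrays spread more widely in these 3. For the macrophage list the Ocn+ arrays lie below the Osx+ arrays, by a narrow margin.

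The late steps of bone formation showed small list differences. Osteocyte genes stood at 10.73 ± 0.11 in Ocn+ cells (SD, n = 3) and 10.18 ± 0.50 in Osx+ cells (SD, n = 4), and 11 of 13 members had a difference above 0. The list rose by 0.55, with a camera adjusted p of 0.00344 and an adjusted p of 0.356 with an estimated correlation. Fam20c, a kinase of secreted matrix proteins, differed by 0.67 (SE 0.23) and Fgf23, a phosphate-regulating hormone of osteocytes, by 0.73 (SE 0.26). Mepe and Sost, osteocyte genes chosen after their values were seen, differed by 2.61 (SE 1.08) and 1.07 (SE 0.53). Of 20 mature osteoblast genes 13 were measured, without Bglap, Bglap2, Bglap3, Spp1, Ifitm5, Lipc and Slc36a2. The measured ones stood at 11.70 ± 0.26 in Ocn+ cells (SD, n = 3) and 11.23 ± 0.47 in Osx+ cells (SD, n = 4), with 9 of 13 above 0. This list rose by 0.47, with a camera adjusted p of 0.0148 and an adjusted p of 0.575 with an estimated correlation. The potassium channel Kcnk2 differed by 1.12 (SE 0.29) and the Wnt inhibitor Dkk1 by 1.13 (SE 0.43), and 0 members of either list passed over all genes or adjusted over the list alone. Without Osx+ replicate 1 the osteocyte difference was 0.35 (adjusted p = 0.162) and the mature osteoblast difference 0.30 (adjusted p = 0.372). The mature osteoblast call was also lost without Ocn+ replicate 2 (adjusted p = 0.0951) and without Ocn+ replicate 3 (adjusted p = 0.141). With the Xist class in the model neither passed, at adjusted p = 0.0958 for osteocyte and 0.327 for mature osteoblast genes, with differences of 0.53 and 0.42. Among high-Xist and low-Xist libraries the osteocyte difference was 0.56 and 0.48, and the mature osteoblast difference 0.52 and 0.27. Within the high-Xist libraries neither list passed (adjusted p = 0.129 and 0.290). The mature osteoblast call was also lost with array weights (0.41, adjusted p = 0.116) and with genes under the median signal left out (0.41, adjusted p = 0.125).

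Early osteolineage genes did not pass, with a mean difference of 0.14 (adjusted p = 0.766), which was 0.06 without Osx+ replicate 1, 0.24 without Ocn+ replicate 1 and 0.23 without Osx+ replicate 4. Among them the transcription factor Dlx3 differed by 1.16 (SE 0.49) and the matrix glycoprotein Tnc by -0.31 (SE 0.13). Genes of mineralization and phosphate handling differed by 0.07 (adjusted p = 0.839), with the secreted stanniocalcins apart from each other, Stc1 at 1.37 (SE 0.54) and Stc2 at -1.26 (SE 0.38). Stromal progenitor and hematopoietic niche genes differed by 0.25 (adjusted p = 0.222) and passed with the mean of all probe sets per gene (0.32, adjusted p = 0.0285) or the probe set of largest variance (0.47, adjusted p = 0.0162), with Cxcl12, the chemokine that retains progenitors in marrow, at 0.74 (SE 0.37) and the adhesion molecule Vcam1 at -0.37 (SE 0.26). Lymphoid support and homing genes had a mean difference of 0.16 and a test in the other direction (adjusted p = 0.898). Within that list the B cell chemokine Cxcl13 differed by -0.52 (SE 0.17) and Selp, an adhesion molecule of platelets and endothelium, by 2.62 (SE 1.17).

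Extracellular matrix lists did not pass either. Fibrillar and network collagens differed by 0.14 in the mean and -0.05 in the median, and their test ran downward (adjusted p = 0.812), with Col8a1 at 1.45 (SE 0.37) and Col12a1 at -1.06 (SE 0.38). Matrix glycoproteins and proteoglycans differed by 0.05 (adjusted p = 0.898), with periostin (Postn), a protein of periosteum, at -1.04 (SE 0.28) and fibrillin Fbn2 at 1.29 (SE 0.52). Matrix proteases and inhibitors differed by 0.14 (adjusted p = 0.898), and their leading members were Ctsk and Mmp9. Without Osx+ replicate 1 that difference was 0.0039 and without Osx+ replicate 3 it was 0.31.

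Among blood cell lists, hematopoietic stem and progenitor genes stood at 7.67 ± 0.11 in Ocn+ cells (SD, n = 3) and 7.21 ± 0.19 in Osx+ cells (SD, n = 4). The list rose by 0.46, with a camera adjusted p of 0.00197 and an adjusted p of 0.356 with an estimated correlation, and its arrays did not overlap. Fry, which tests whether the genes of a list move on balance one way, also called it (adjusted p = 0.0458). The difference was 0.53 among high-Xist libraries and 0.45 among low-Xist libraries. Its member Erg also belongs to the endothelial list, which rose too, and whether the rise comes from blood progenitors was not tested. The members that passed adjusted over the list alone were 2, the transcription factor Gata2 with a difference of 1.84 (SE 0.17) and the stem cell factor receptor Kit with 1.51 (SE 0.25). The other Kit probe set differed by 0.72 (SE 0.41), and its groups overlapped. Both belong to the mast cell and basophil list too, which rose by 0.41 (camera adjusted p = 0.0411). Its adjusted p was 0.583 with an estimated correlation. The mast cell call was lost without Ocn+ replicate 1 (difference 0.04, adjusted p = 0.142), without Ocn+ replicate 2 (0.29, adjusted p = 0.0951), without Osx+ replicate 1 (0.20, adjusted p = 0.288) and without Osx+ replicate 4 (0.11, adjusted p = 0.235). Without Ocn+ replicate 3 and without Osx+ replicate 3 its difference was 0.89 and 0.91. The call was also lost with the Xist class in the model (0.57, adjusted p = 0.149), within high-Xist libraries (0.48, adjusted p = 0.298) and with the mean of all probe sets per gene (0.35, adjusted p = 0.0973). The mast cell difference was 0.70 among low-Xist libraries, 0.73 with genes under the 25th percentile of signal left out and 0.79 with array weights.

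Chemokines fell by 0.36 in Ocn+ cells, with a camera adjusted p of 0.0422 and an adjusted p of 0.746 with an estimated correlation. The platelet chemokines Ppbp and Pf4 led, at -2.29 (SE 0.53) and -1.11 (SE 0.48). Without Ocn+ replicate 2 the chemokine difference was 0.0023 (adjusted p = 0.877), and without Osx+ replicate 1 it was -0.13 (adjusted p = 0.372). It did not pass without Ocn+ replicate 3 (-0.30), Osx+ replicate 2 (-0.46) or Osx+ replicate 3 (-0.25), and was -0.79 without Ocn+ replicate 1 and -0.61 without Osx+ replicate 4. With the Xist class in the model it was -0.17 (adjusted p = 0.696), with -0.26 among high-Xist (adjusted p = 0.566) and -0.034 among low-Xist libraries. The chemokine call was also lost with array weights (adjusted p = 0.0971), with genes under the median signal left out (0.0739) and with median centring (0.0633). Megakaryocyte and platelet genes as a list differed by 0.06 (adjusted p = 0.973), and 1 member, Ppbp, passed adjusted over the list alone. T and NK cell genes differed by 0.22 (adjusted p = 0.217), and the surface receptor Cd5 and the granule protein Nkg7 passed adjusted over the list alone, at 1.41 (SE 0.26) and 1.80 (SE 0.42). Lymphoid markers were dim, with a T and NK list mean of 5.76 in Ocn+ and 5.54 in Osx+ cells.

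The remaining blood lists did not pass in the main comparison of all 7 arrays, though erythroid genes passed in other settings given with the processing below. B cell genes differed by -0.15 (adjusted p = 0.334), with Il7r at -1.45 (SE 0.71) and Cd22 at -1.14 (SE 0.58). Plasma cell genes differed by 0.12 (adjusted p = 0.625), with Prdm1 at 0.79 (SE 0.46) and Sdc1 at 0.14 (SE 0.15). Dendritic cell genes differed by 0.26 (adjusted p = 0.556), with Zbtb46 at 1.30 (SE 0.64) and Ccr9 at -0.55 (SE 0.22). Erythroid genes differed by -0.29 (adjusted p = 0.0610), with 15 of 16 members below 0 and the hemoglobin gene Hba-a1 at -0.31 (SE 0.18) and Epb42 at -0.19 (SE 0.16). The erythroid list passed without Ocn+ replicate 1 (-0.74, adjusted p = 0.000269), Osx+ replicate 3 (-0.33, adjusted p = 0.0448) or Osx+ replicate 4 (-0.56, adjusted p = 0.00313), and was above 0 without Ocn+ replicate 3 (0.13) or Osx+ replicate 1 (0.07).

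Other cell types of the marrow space did not pass in the main comparison of all 7 arrays, though pericyte genes passed with the probe set of largest variance per gene. Pericyte and smooth muscle genes differed by 0.46 (adjusted p = 0.234), with Rgs5 at 1.38 (SE 0.43) and Mcam at 1.75 (SE 0.55), both also expressed in vessels. This list passed without Osx+ replicate 3, with a difference of 0.74 (adjusted p = 0.00479), and its difference was 0.25 without Ocn+ replicate 1 and 0.28 without Osx+ replicate 2. Adipocyte genes differed by 0.20 in the mean and -0.04 in the median (adjusted p = 0.898), with the adipokine Adipoq at 1.80 (SE 0.49) and the fatty acid carrier Fabp4 at 1.67 (SE 0.84). Schwann and neural genes differed by -0.11 (adjusted p = 0.766), with Tubb3 at -0.78 (SE 0.42) and S100b at 0.61 (SE 0.47). Skeletal muscle genes differed by 0.17 (adjusted p = 0.812), with Myh4 at -0.18 (SE 0.20) and Actn3 at 0.60 (SE 0.69).

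In signaling, IGF and FGF genes rose by 0.32 in Ocn+ cells, with a camera adjusted p of 0.0331 and an adjusted p of 0.356 with an estimated correlation. Spry1, a feedback inhibitor of FGF signaling, passed adjusted over the list alone at 1.27 (SE 0.23), and Fgf18 differed by 0.85 (SE 0.36). The call was lost without Ocn+ replicate 1 (difference 0.21, adjusted p = 0.0689), Ocn+ replicate 3 (0.34, adjusted p = 0.101), Osx+ replicate 1 (0.31, adjusted p = 0.261) or Osx+ replicate 4 (0.26, adjusted p = 0.0586), and with the Xist class in the model (0.37, adjusted p = 0.0577). It was also lost with genes under the 25th percentile (adjusted p = 0.0781) or the median of signal (0.153) left out, with array weights (0.0801) and within high-Xist libraries (0.0621). The difference was 0.40 among high-Xist and 0.33 among low-Xist libraries. Wnt signaling genes differed by 0.21 and did not pass camera (adjusted p = 0.0742), while fry called them (adjusted p = 0.0458) and their arrays did not overlap. Wnt16 differed by 1.21 (SE 0.33) and the secreted Wnt modulator Sfrp2 by 0.65 (SE 0.19). Without Ocn+ replicate 1 the Wnt list passed camera (0.19, adjusted p = 0.0308). BMP and TGF-beta genes differed by 0.19 (adjusted p = 0.0813), with the BMP antagonist Nog at 1.09 (SE 0.37) and Tgfbi at -0.44 (SE 0.19). The BMP and TGF-beta list passed without Ocn+ replicate 1 (0.23, adjusted p = 0.0168), Osx+ replicate 2 (0.19, adjusted p = 0.0307) or Osx+ replicate 4 (0.23, adjusted p = 0.0444).

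Metabolic lists moved little. Cholesterol and lipid synthesis genes fell by 0.32 in Ocn+ cells, with a camera adjusted p of 0.000377 and an adjusted p of 0.575 with an estimated correlation. Of its 19 members 17 had a difference below 0, among them the synthase Hmgcs1 at -0.53 (SE 0.17) and the epoxidase Sqle at -0.83 (SE 0.36). This difference was -0.18 without Ocn+ replicate 3 and -0.21 without Osx+ replicate 2 (adjusted p = 0.0544), and it was -0.48 among high-Xist and -0.11 among low-Xist libraries. Oxidative phosphorylation genes rose by 0.13, with a camera adjusted p of 0.0115 and an adjusted p of 0.746 with an estimated correlation. Of its 33 members 29 had a difference above 0, with Uqcrfs1 at 0.36 (SE 0.16) and Sdhc at 0.29 (SE 0.14). That call was lost without Ocn+ replicate 1 (0.06, adjusted p = 0.1004), Osx+ replicate 2 (0.07, adjusted p = 0.0656) or Osx+ replicate 4 (0.08, adjusted p = 0.118), or with the probe set of largest variance per gene (0.12, adjusted p = 0.0594), and the difference was 0.19 without Osx+ replicate 1. It was 0.21 among high-Xist and 0.11 among low-Xist libraries. Glycolysis and hypoxia genes differed by -0.10 (adjusted p = 0.0813), with the vasoactive peptide Adm at 1.00 (SE 0.30) and the glycolytic enzyme Pfkp at -0.63 (SE 0.24), and the list passed without Osx+ replicate 3 (-0.14, adjusted p = 0.0480).

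Growth and stress lists did not pass in the main comparison of all 7 arrays, and 3 of them passed with 1 array left out. Cell cycle and immediate early genes also passed in other settings, given with the processing below. Cell cycle genes differed by -0.12 (adjusted p = 0.0742), with Mcm4 at -0.50 (SE 0.24) and Rrm2 at -0.32 (SE 0.19). Without Ocn+ replicate 1 and without Osx+ replicate 3 the cell cycle difference was -0.24, and the list passed (adjusted p = 0.00271 and 0.00116). Ribosomal protein genes differed by -0.02 (adjusted p = 0.556), with Rps24 at -0.11 (SE 0.14) and Rps6 at -0.15 (SE 0.19). Immediate early and dissociation stress genes differed by 0.13 (adjusted p = 0.0610), with Ier2 at 0.56 (SE 0.31) and Btg2 at 0.25 (SE 0.15). That list passed without Ocn+ replicate 1 (0.10, adjusted p = 0.0400) and without Osx+ replicate 3 (0.18, adjusted p = 0.0379). Interferon response genes differed by 0.25 (adjusted p = 0.150), with Mx2 at 0.91 (SE 0.38) and Oas2 at 0.55 (SE 0.33). The interferon list passed without Ocn+ replicate 2 (0.57, adjusted p = 0.000140) and was -0.15 without Ocn+ replicate 1. Unfolded protein response and secretion genes differed by -0.05 (adjusted p = 0.238), with the chaperone Hspa5 at -0.25 (SE 0.17) and Dnajc3 at -0.34 (SE 0.23). Apoptosis and p53 target genes differed by 0.09 (adjusted p = 0.243), with Gadd45a at 0.99 (SE 0.25) and Plk2 at 0.43 (SE 0.18).

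The single genes with the smallest p in each direction did not pass, with limma adjusted p between 0.108 and 0.689. With array weights 19 of these 24 passed, which adds no independent support, since the genes and the weights came from the same arrays. Higher in Ocn+ cells, Gata2 stood at 9.60 ± 0.17 (SD, n = 3) against 7.76 ± 0.15 (SD, n = 4), and its other probe set differed by 1.41. Kcne3, a potassium channel subunit, was 11.9-fold brighter (log2 difference 3.57, SE 0.44), and Lrg1, a secreted glycoprotein made by neutrophils and vessels, was 5.95-fold brighter (2.57, SE 0.33). Next came Oscar, Cdh5, Kit, Spry1 and Cd5, given above, Cebpb, a transcription factor of myeloid cells and osteoblasts (1.20), the hemoglobin scavenger Hp (1.68), the glutathione transferase Gstm6 (1.30) and Tmem191c (0.85). Lower in Ocn+ cells were Vnn3 (-1.26, SE 0.16), the prostaglandin D synthase Hpgds (-1.83, SE 0.30), Rassf5 (-0.91), the stathmin Stmn4 (-2.05) and dermatopontin (Dpt), a matrix protein (-1.18). Also lower were Dnajc2 (-1.18), Zfp189 (-1.04), Calm4 (-1.46), Nsg2 (-1.51), Hs3st3a1 (-0.75), Adap2 (-1.92) and Tlr1, a receptor of bacterial lipoproteins (-2.21). Dnajc2 differed by 0.02 when its probe set of largest variance was used.

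The arrays split on something other than their group. Xist, the transcript of the inactive X chromosome, was low in Ocn+ replicate 1 (5.47), Osx+ replicate 1 (4.87) and Osx+ replicate 3 (5.79), and between 12.33 and 12.96 in the other 4. The first principal component held 49.9% of the variance and separated these 2 classes, with the second at 20.3%. The mean correlation over genes was 0.961 between arrays of the same group and 0.965 between groups, but 0.978 within a Xist class and 0.952 between classes, where genes are not independent replicates. Between the classes limma called 2485 genes, 1467 of them higher in the low-Xist libraries. With the class as a term beside the group, limma called 0 genes and camera 9 lists, all 9 among the 14. Within the 4 high-Xist libraries limma called 19 genes, 17 of them higher in Ocn+ cells, among them Oscar, Flt4, Mcam, Selp and Notch4, and within the 3 low-Xist libraries it called 0 (268 at an unadjusted p under 0.05). The low-Xist fit sets 1 Ocn+ library against 2 Osx+ libraries and assumes that the lone library varies like the others, so its count is no measure against the 19.

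**Figure D3:**
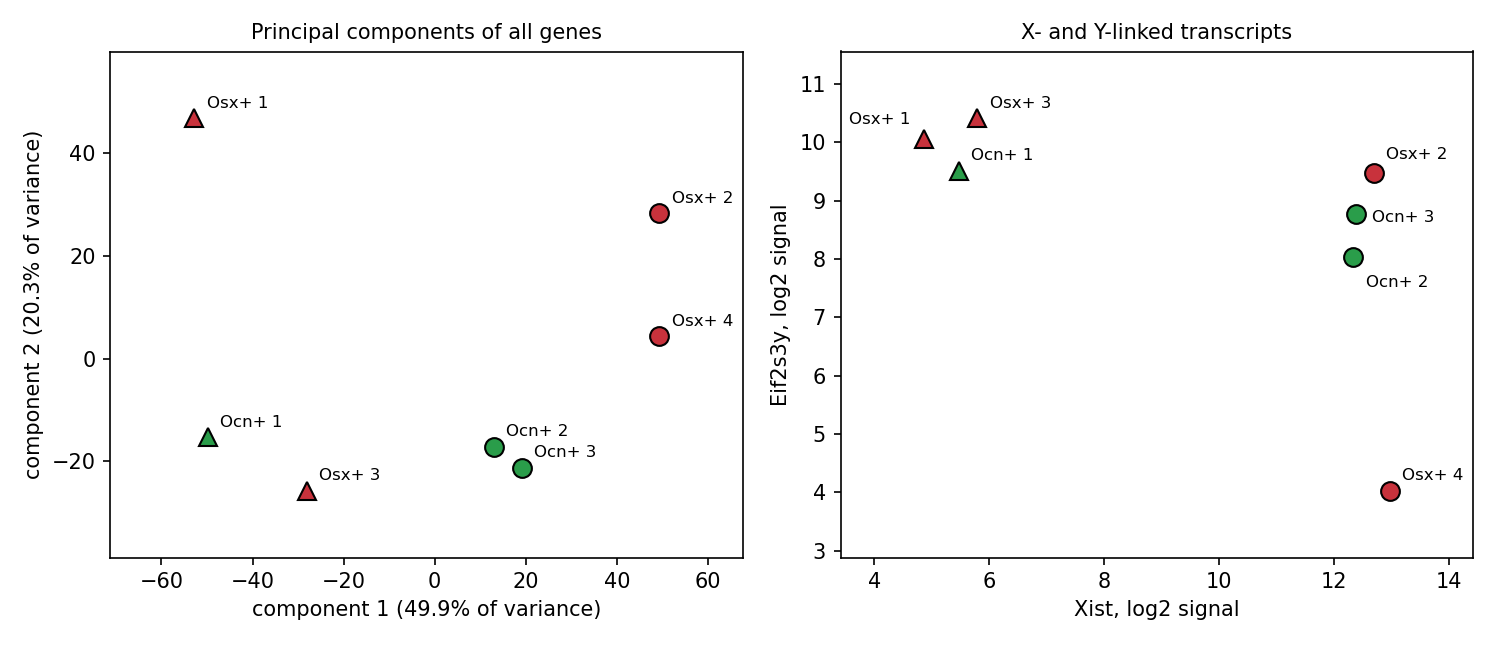
Left, the 7 arrays on the first and second principal components of all genes (49.9% and 20.3% of the variance). Right, log2 signal of the X-linked Xist against the Y-linked Eif2s3y; red is Osx+, green is Ocn+, triangles are low-Xist and circles high-Xist libraries. The low-Xist arrays lie left of the high-Xist arrays, and Ocn+ replicates 2 and 3 and Osx+ replicate 2 have both signals.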

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

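The test used here, a gap between 1 library and its nearest neighbour over 0.829 of the range of the 4 Osx+ libraries, was set in advance, and Elane, Epx, Prg3 and Ckmt1 were among the genes chosen after their values were seen. Of 162 genes and lists examined 10 met it, where chance gives about 8, so their number is close to what chance gives; the Ocn+ group of 3 was not tested.

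Osx+ replicate 2 stood apart for 4 genes. The granule protease genes Prtn3 and Elane were at 9.78 and 8.18 there, against 5.58 to 6.20 and 3.95 to 4.44 in the other Osx+ libraries. Adap2 was at 9.36 against 8.07 to 8.21, and Adm at 7.51 against 8.40 to 8.53. Osx+ replicate 3 stood apart for the protease gene Ctsk, at 13.1 against 12.4 to 12.5, for the creatine kinase gene Ckmt1, at 7.10 against 4.43 to 4.66, and for the eosinophil peroxidase gene Epx, at 5.24 against 4.80 to 4.86. Osx+ replicate 1 stood apart for Stmn4, at 9.31 against 8.01 to 8.23, for the eosinophil granule gene Prg3, at 7.13 against 3.85 to 4.28, and for the T and NK cell list, with a mean of 5.85 against 5.41 to 5.47.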

How the results depend on the processing

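The fits that use the Xist class were chosen after seeing the data, and the other settings were fixed before. Sp7 stayed above 0 and short of the threshold in every fit run, with differences of 0.043 to 0.38. The endothelial (1.11 to 2.89), neutrophil (1.31 to 2.17), osteoclast (0.80 to 1.66), macrophage (-1.03 to -0.47) and chondrocyte (-1.45 to -0.46) lists kept their direction and call in every setting that used camera's preset correlation, and lost the call with an estimated correlation and with fry. The fit within low-Xist libraries has 1 Ocn+ library, assumed to vary like the Osx+ libraries, so its calls add no support. Over all settings, lists stayed on their side of the threshold 703 times, lost a call 78 times, gained one 38 times and reversed 35 times. Apart from arrays left out, the block and fry, calls were gained by cell cycle with both filters on dim genes, array weights and the high-Xist libraries, glycolysis with both filters and Wnt with the 25th percentile. Notch targets, immediate early and stromal progenitor genes gained one with both other probe set rules, erythroid with the mean of probe sets, BMP and pericyte with the largest variance, and interferon and skeletal muscle in low-Xist libraries. Single genes stayed 2165 times, gained a call 48 times and reversed 10 times. Since the main fit called 0 genes, none could lose a call, so the number that stayed is no measure of stability. Leaving out genes under the 25th percentile or the median of signal also gave 0 genes in limma (512 and 312 at an unadjusted p under 0.05), so dim genes alone do not account for the count. In simulated data of 3 against 4 arrays, 19.5% of changes of 1 log2 unit and 77.9% of those of 2 were recovered. Those rates are for randomly chosen genes with independent noise and do not give the power of the real comparison. In the real data 58 genes differed by at least 2 log2 units, and 0 genes passed.

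The count of 0 genes became 97 with array weights, where Ocn+ replicate 2 had a weight of 6.02, and 19 within high-Xist libraries, and ranged from 0 to 3 when 1 array was left out. The weights were 0.24 to 0.46 for low-Xist and 1.03 to 6.02 for high-Xist libraries. The weighted fit therefore leans on the high-Xist libraries and is not independent of the fit within them. The count of 14 lists ranged from 9 to 18 when 1 array was left out. It was 9 with the Xist class as a term, 9 within low-Xist libraries, 0 with an estimated correlation and 2 with fry. The cause was not tested.

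With the replicate number as a block, limma called 0 genes (828 at an unadjusted p under 0.05) and camera 14 lists, 11 of them shared with the fit without it. Number 4 has no Ocn+ array, so the block takes Osx+ replicate 4 out of the group difference. The list differences therefore equal those without that array. The block added the stromal progenitor (0.30, adjusted p = 0.0456), BMP and TGF-beta (0.23, 0.0223) and erythroid (-0.56, 8.40e-05) lists. Without Osx+ replicate 4 alone, BMP and TGF-beta (0.0444) and erythroid (0.00313) also passed, and stromal progenitor did not (0.118). The block left out IGF and FGF (0.26, 0.0626), mast cell (0.11, 0.261) and oxidative phosphorylation (0.083, 0.188), calls also lost without Osx+ replicate 4 alone. The Sp7 difference was 0.30. Deviations of same-numbered arrays correlated at 0.63, 0.45 and -0.30, and for number 1 alone did both arrays correlate best with their own number. The numbers were therefore not taken to pair the arrays. The matrix glycoprotein (-0.0030), dendritic cell (-0.033) and megakaryocyte (-0.082) lists reversed under the block. They did so by the same values without Osx+ replicate 4 alone.

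The cause of the other reversals was not tested. Leaving out 1 array at a time gave ranges that crossed 0 for 13 lists. These were mineralization (-0.052 to 0.15), lymphoid support (-0.0036 to 0.28), chemokines (-0.79 to 0.0023), matrix glycoproteins (-0.0030 to 0.12), B cell (-0.34 to 0.097), dendritic cell (-0.033 to 0.53), erythroid (-0.74 to 0.13) and megakaryocyte (-0.16 to 0.24). The others were Schwann and neural (-0.28 to 0.13), skeletal muscle (-0.31 to 0.51), ribosomal proteins (-0.038 to 0.0039), interferon (-0.15 to 0.57) and unfolded protein response (-0.11 to 0.019). Another 12 lists that did not pass moved by over 1.5 times without crossing 0. These were early osteolineage (0.059 to 0.24), stromal progenitor (0.14 to 0.32), collagens (0.073 to 0.26), matrix proteases (0.0039 to 0.31), BMP and TGF-beta (0.12 to 0.23), adipocyte (0.13 to 0.24), pericyte (0.25 to 0.74), plasma cell (0.020 to 0.27), cell cycle (-0.24 to -0.053), glycolysis (-0.14 to -0.042), immediate early (0.083 to 0.18) and apoptosis (0.059 to 0.13). The T and NK list was -0.21 with genes under the 25th percentile left out. With array weights Rps6 was 0.017, skeletal muscle -0.14 and ribosomal proteins 0.020. With the mean of all probe sets Pfkp was 0.081, Rps6 0.14 and ribosomal proteins 0.011. With the probe set of largest variance Dnajc2 was 0.015, Vcam1 0.11, Rrm2 0.29, Pfkp 0.80, Rps6 0.42, glycolysis 0.014 and ribosomal proteins 0.041. With the Xist class as a term Schwann and neural was 0.011. Within high-Xist libraries Rps6 was 0.068, Schwann and neural 0.14 and ribosomal proteins 0.040. Within low-Xist libraries mineralization was -0.11, matrix proteases -0.026, B cell 0.020, erythroid 0.10, cell cycle 0.23 and Prg3 -1.93.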

Other observations

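Of the tests in this part, the count of lists over other splits and the test of cross-hybridisation were set before their results were seen, and the others after. Of 3 granule genes of eosinophils, in no fixed list and chosen after their values were seen, 0 passed in limma with equal array weights, and as a group they were not tested. With arrays weighted by their fit, Prg2 and Epx passed (adjusted p = 0.0303 and 0.0491). Prg2, the major basic protein, stood at 6.79, 12.24 and 10.67 in the Ocn+ libraries and between 4.17 and 5.05 in the 4 Osx+ libraries. Its difference was 5.35 (SE 1.15), with a limma adjusted p of 0.689, and whether the Osx+ values lie above background is not known. Epx, the eosinophil peroxidase, stood at 5.80, 9.18 and 7.92 against 4.80 to 5.24, a difference of 2.69 (SE 0.71, adjusted p = 0.731). Prg3 overlapped between the groups, at 3.78, 6.55 and 6.32 in the Ocn+ libraries and 7.13, 3.85, 4.28 and 3.89 in the Osx+ libraries, a difference of 0.76 (SE 1.00, adjusted p = 0.999). Among high-Xist libraries the differences of Prg2, Epx and Prg3 were 6.63, 3.72 and 2.56, of which that of Prg3 passed (adjusted p = 0.0434), and among low-Xist libraries 2.53, 0.75 and -1.93.

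The values of Mpo, Camp and Mepe, chosen after they were seen, are given per library, and spread was not tested. Mpo, the myeloperoxidase of azurophil granules, stood between 11.75 and 11.93 in the Ocn+ libraries and at 8.62, 11.30, 7.88 and 5.93 in Osx+ replicates 1 to 4. Camp, a peptide of specific granules, stood between 12.40 and 12.76 in Ocn+ libraries and at 11.10, 12.39, 8.63 and 8.16 in Osx+ libraries. Mepe, a matrix protein of osteocytes, stood between 10.35 and 11.44 in Ocn+ libraries and at 5.52, 7.55, 10.17 and 9.59 in Osx+ libraries. The adjusted p of these genes was 0.888, 0.935 and 0.935 in limma.

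Dll4 and the endothelial list were higher together in Ocn+ libraries, and the brightest members of the list were Ramp2 (11.39 against 10.59), Plvap (10.89 against 7.97), Stab1 (10.56 against 11.28) and Emcn (10.47 against 7.61). Of the 20 members 2 belong to another fixed list, 2 lay above the median gene in Osx+ cells and 15 did so in Ocn+ cells, and the labels name a sort by reporter colour with no endothelial gate. With the other cells in the same mix, a lower share of osteolineage cells in the Ocn+ libraries would raise every other cell type's markers. The macrophage list instead differed by -0.82 (SE 0.39) and parted from the endothelial list by 2.81 (SE 0.88). These values cannot address a mix of other cells that differs between the sorts, which stays open. Unequal Xist classes would remove the endothelial difference once modelled, but it was 2.18 (SE 0.56). Endothelial RNA in the Ocn+ libraries may account for the Dll4 signal, since with the list mean as a covariate the Dll4 difference went from 1.85 to 0.77 (95% interval -0.096 to 1.64), although the list mean itself separates the groups and part of Dll4 may still come from bone cells. In the same fit Dll1 went from 1.33 to 1.13 (SE 0.50). With the multiple of the SE used for Dll4, its interval also holds 0. Jag1 (0.33, SE 0.48) and Notch2 (0.50, SE 0.35) stood above 0. Notch4 (-0.60, SE 0.35), Notch3 (-0.30, SE 0.25), Jag2 (-0.51, SE 0.40), Notch1 (-0.48, SE 0.38), Dll3 (-0.23, SE 0.27) and Dlk1 (-1.01, SE 0.77) stood below 0. Apart from Dll4 and Dll1, each lay within 2 SE of 0, so these signs do not divide the Notch genes. Whether Ocn+ cells themselves make more Dll4 or Dll1, a difference the design names, was not tested and stays open.

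The strongest structure in these arrays was the split by Xist signal, which called 2485 genes. X and Y gene dosage as the whole cause would put most of them on those chromosomes, but 68 of 2482 with a known chromosome, or 2.74%, lay there, against 3.31% of genes tested. RNA integrity or amplification length may differ between the classes, since the mean 3' minus 5' signal of the 4 mouse control transcripts was 2.09 ± 0.22 (SD, n = 3) in low-Xist and 1.48 ± 0.09 (SD, n = 4) in high-Xist libraries. That difference was 0.61, with an exact permutation p of 0.0571, the smallest 3 against 4 can give. Taken singly, the Gapdh and pyruvate carboxylase controls separated the classes, and the actin and transferrin receptor controls overlapped between them. Sex of the animals beyond gene dosage stays open, as untested.

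Ocn+ replicates 2 and 3 and Osx+ replicate 2 carried both Xist (12.33, 12.37 and 12.68) and the Y-linked Eif2s3y (8.03, 8.78 and 9.47), while Osx+ replicate 4 had Xist at 12.96 and Eif2s3y at 4.03. Cross-hybridisation of the X-linked copy Eif2s3x to the Y-linked probe set would need less Eif2s3x in Osx+ replicate 4, but it was 0.20 above the mean of 12.56 in the other 3. RNA of both sexes, as from pooled animals, is a candidate explanation for these 3 libraries. The labels do not say whether animals were pooled, and no biological explanation was tested.

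Chance cannot be excluded for the count of lists between the groups. Of the 35 splits of the 7 arrays into 3 and 4, 7 gave at least the real 14 lists, and the highest other count was 22. For genes past the threshold the real count was 0, which all 35 splits reach whatever the data, so their number says nothing about chance. At an unadjusted p under 0.05, where the real split gave 658 genes, 12 of the 35 splits gave at least as many and the highest other count was 4491, so chance cannot be excluded for that count. The split that follows the Xist class gave the 4491 genes, 2485 of them past the threshold, and 4 lists, which points to a structure of the samples. With the Xist class as a term 0 genes and 9 lists were called between the groups.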
